A study of Mus musculus with 12 samples.

How the data were processed

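Small RNA libraries of 6 WT and 6 db/db samples of cardiac mitochondria were analysed from 1 table with a column for each sample. Per the labels' protocols, total RNA was ligated to adapters at both ends, reverse transcribed, amplified and size selected on a gel. The authors deposited the values under the name TPM. Each column sums to 1000000 and its values are whole multiples of the worth of 1 read, the same for every miRNA, so the deposited unit was taken as RPM, reads scaled to that sum, with no length term. The mouse genome build was GRCm39, per the submitters' processing notes; the aligner, the miRNA annotation and the caller of unnamed miRNAs are not given in the sources used here. The deposited table lists 932 rows: 730 with a mouse miRNA name and 202 named only by a chromosome and a number, which held 0.0574 to 0.160% of reads per library. 85 rows were 0 in every library. Among the 531 rows above 0 in at least 3 libraries, 8 rows in 4 sets were identical to another row in all 12 libraries, among them let-7a-1-3p and let-7c-2-3p; sparser rows, not counted here, also coincide.

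Reads were recovered from RPM with 1 whole library total per column: 100% of values came out whole within 0.01 of a read. Totals ranged from 412749 to 1382046 reads. A value of 0 allows up to 3 reads, or 2.17 to 7.27 RPM. These limits cover counting error only, since PCR copies are not independent. No pair among the 66 pairs of libraries agreed within sampling noise (lowest chi-square per degree of freedom 18.6).

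The design, the lists, the tests and most alternatives were fixed before the data were examined. The design assumed TPM; the test on a log scale was kept for RPM. The main test was limma 3.58.1 in R 4.3.3 with an abundance trend on log2(RPM + 1), over 646 rows with a mean of at least 1 RPM (513 named, 133 unnamed), without a replicate block. Fold changes are differences of group means on this scale, which for low miRNAs can lie above or below the log2 ratio of the mean RPM. p-values were two-sided with Benjamini-Hochberg adjustment, called under 0.05. 21 lists of at least 3 tested members were tested with camera at a preset correlation of 0.01. Single values were compared by exact permutation over 924 assignments. Recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0, which left 501 adjusted p missing. Other alternatives were the pseudocount, the filter, the scaling, the trend, library weights, the replicate block, each library left out, an estimated correlation and fry. Chosen after seeing the data were a mean of at least 100 RPM, named rows alone, leaving out WT 4 and db/db 6, miR-486a-5p and miR-486b-5p as 1, numbers 1 to 3 and 4 to 6 as a factor, and edgeR with the block or with that factor.

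Named miRNAs were, by rule, up to 10 called in each direction with a mean of at least 10 RPM in a genotype, the 6 most abundant, 13 fixed names, up to 3 called members of each called list and, with fewer than 10 calls, the 10 with the smallest p. Other list members, miR-24-3p, miR-125a-5p and the miRNAs that differ by number were chosen after their values were seen.

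Positions of precursors were taken from GENCODE M21 and a GRCm38.p6 gene table, for host genes alone, since the build differs from that of the table; no coordinates are given. On 646 simulated rows of the comparison of db/db with WT, limma recovered 5 of 67 changes of 1.5-fold, 8 of 67 of 2-fold and 17 of 66 of 4-fold. In rows with a mean of at least 100 RPM it recovered 4 of 16, 7 of 17 and 10 of 10. Of 32 calls 2 were false. Python 3.11.15 and matplotlib 3.10.9 drew the plots.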

Results

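Small RNA was sequenced from mitochondria isolated from mouse hearts. The 12 libraries comprised 6 from wild-type (WT) mice and 6 from db/db mice, which lack a working leptin receptor and become obese and diabetic. The labels number the samples of each genotype 1 to 6 but do not say that each came from a separate animal, so p-values measure the spread between these samples, which may be technical. The values were in RPM, reads scaled to a common library total. A read assigned to more than 1 row would count in each. The recovered depth, the reads of all listed rows, ranged from 412749 reads in db/db library 6 to 1382046 reads in db/db library 5. It averaged 747539 ± 159277 reads (SD, n = 6) in WT and 798579 ± 316652 (SD, n = 6) in db/db libraries, a difference within the spread between libraries (exact permutation test, two-sided, p = 0.777). One read was therefore worth 0.724 to 2.42 RPM, and miRNAs below about 10 RPM rested on few reads.

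The libraries had the profile of heart muscle in both genotypes. miR-133a-3p, a miRNA of cardiac and skeletal muscle, was the most abundant miRNA in all 12 libraries. It held 32.4% ± 2.28 of reads in WT and 34.1% ± 2.76 in db/db libraries (SD, n = 6 each; exact permutation test, two-sided, p = 0.268). miR-1a-3p, which is transcribed with miR-133a in muscle, followed at 62696 ± 11812 RPM in WT and 53914 ± 16810 RPM in db/db libraries (SD, n = 6 each). The next in mean abundance were miR-125b-5p, miR-30d-5p, miR-30a-5p and miR-378a-3p. The last of these, whose gene lies in an intron of Ppargc1b, stood at 29173 ± 3138 RPM in WT and 27257 ± 2616 RPM in db/db libraries. The 10 most abundant miRNAs of each library together held 63.0% ± 1.01 of reads in WT and 63.3% ± 2.18 in db/db libraries (SD, n = 6 each; exact permutation test, two-sided, p = 0.716). The number of listed miRNAs above 0 averaged 437.3 in each genotype (exact permutation test, two-sided, p = 1), with a range of 404 to 507.

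The comparison of db/db with WT asked how miRNAs in these preparations of cardiac mitochondria differ in this diabetic model. No other fraction was among the libraries, so the location of a miRNA in mitochondria and the purity of the preparations were not tested. miR-22-3p, an abundant miRNA of heart and skeletal muscle, was lower in db/db libraries. It fell from 17708 ± 3699 RPM in WT to 11882 ± 1677 RPM in db/db (SD, n = 6 each), a log2 fold change of -0.56 ± 0.13 (SE; limma adjusted p = 0.0466), and all 6 db/db libraries lay below the WT median. In a GRCm38 annotation its gene lies in exons of the noncoding RNA Mir22hg and of the protein-coding gene Tlcd2, both on the same strand. It was the only one of the 646 miRNAs tested to pass the threshold: 1 was lower and 0 were higher. At an unadjusted p under 0.05 there were 28 higher and 30 lower, against 32.3 in all by chance. The call was lost under 10 of 15 other limma settings and in 7 of the 12 fits that left out 1 library (limma adjusted p up to 0.311). Without an abundance trend in the variance limma gave an adjusted p of 0.691, and after median-of-ratios scaling the calls were 2 higher (miR-486a-5p and miR-486b-5p) and 0 lower. On the recovered reads edgeR called 3 miRNAs (2 higher, miR-486a-5p and miR-486b-5p, and 1 lower) and DESeq2 called 13 (10 higher and 3 lower). At an unadjusted p under 0.05 edgeR had 159 of the 646 rows, against 58 by limma and 45 by DESeq2. DESeq2 left most adjusted p missing and so adjusted over fewer rows. Its count of calls is therefore not directly comparable with the others.

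**Figure D1:**
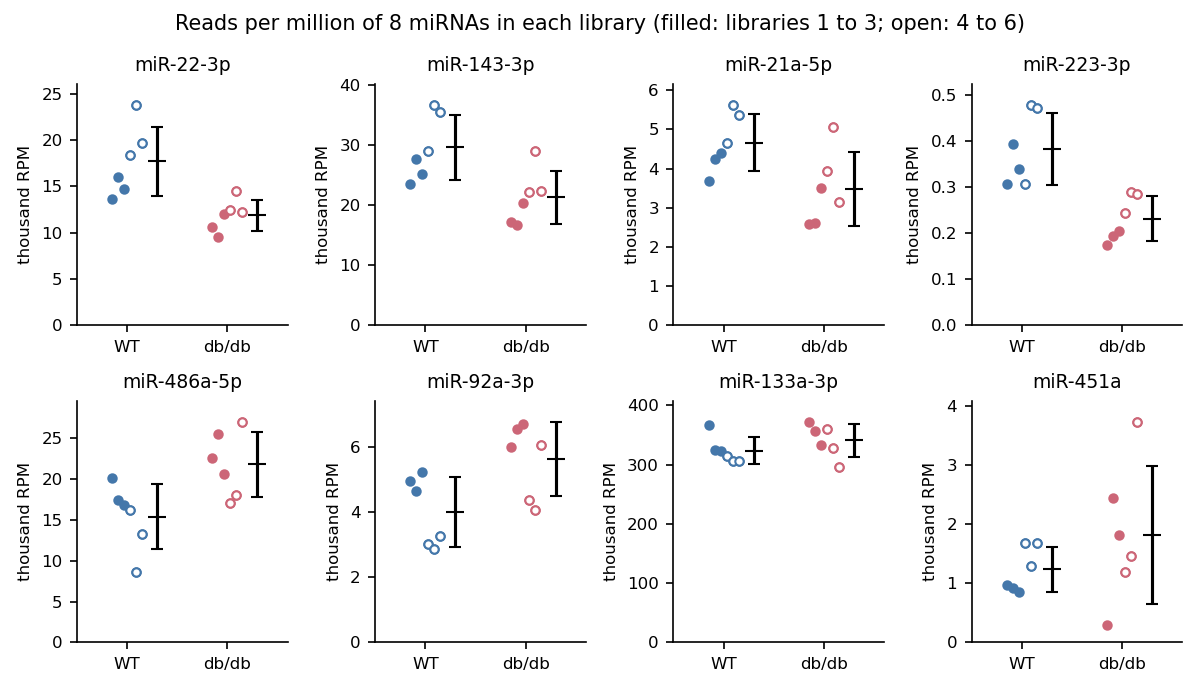
Each panel plots 1 miRNA in RPM (y axis, from 0, in the multiple its title gives) for the 6 WT and 6 db/db libraries; points are libraries (filled for numbers 1 to 3, open for 4 to 6) and the bars at the right of each group are the mean ± SD. miR-22-3p averaged 17708 RPM in WT and 11882 RPM in db/db libraries, while miR-133a-3p differed by less than the spread between libraries.

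Several abundant miRNAs came close to the threshold without passing it in the fit without that factor. miR-486a-5p, a miRNA of muscle and red blood cells encoded in an intron of Ank1, averaged 15389 ± 3987 RPM in WT and 21760 ± 3952 RPM in db/db libraries (SD, n = 6 each; log2 fold change 0.53 ± 0.14, SE; limma adjusted p = 0.0869). miR-486b-5p gave nearly the same values (0.53 ± 0.14, SE); its gene lies on the opposite strand at the same place, so the reads of the 2 miRNAs may not be separable. miR-143-3p, a miRNA of smooth muscle, averaged 29619 ± 5378 RPM in WT and 21295 ± 4450 RPM in db/db libraries (SD, n = 6 each; log2 fold change -0.48 ± 0.13, SE; limma adjusted p = 0.0869). miR-92a-3p, of the miR-17-92 cluster, stood at 0.51 ± 0.15, miR-195a-5p, of the miR-15 family, at -0.62 ± 0.18 and miR-223-3p, a myeloid miRNA, at -0.72 ± 0.22 (log2 fold change, SE; limma adjusted p = 0.109 for each). Lower-count miRNAs had larger fold changes with wider errors. miR-7a-1-3p, from an intron of Hnrnpk, averaged 4.32 ± 5.99 RPM in WT and 24.0 ± 10.2 RPM in db/db libraries (SD, n = 6 each). The arms of miR-434, which lies antisense to Rtl1, had values of opposite sign, miR-434-3p at 2.08 ± 0.63 and miR-434-5p at -1.96 ± 0.58 (log2 fold change, SE; limma adjusted p = 0.109 for each). From the recovered reads edgeR and DESeq2 gave smaller values for miR-434-3p (1.45 and 1.48) and miR-7a-1-3p (2.38 and 2.48, against 2.94 by limma), and -1.92 each for miR-434-5p.

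Fibroblast and smooth muscle miRNAs ranked lower in db/db libraries as a list. Of 11 members 8 had negative values, with a median log2 fold change of -0.33 (camera adjusted p = 0.0137; adjusted p = 0.409 with an estimated correlation). None passed over all miRNAs, while 2 were lower when adjusted over the list alone, miR-143-3p and the stress-responsive miR-21a-5p (-0.45 ± 0.15, SE). miR-145a-5p stood at -0.33 ± 0.14 and miR-214-3p at 0.45 ± 0.22 (SE). This call was lost after median-of-ratios scaling (camera adjusted p = 0.0748), after rescaling without the 10 most abundant miRNAs (0.0920), without a trend (0.110), at a mean of at least 100 RPM (0.140), and without db/db library 2 (0.0551) or 6 (0.0795). The endothelial list (4 of 5 negative, median -0.23) and the leukocyte list (6 of 9 negative, median -0.47) did not pass (camera adjusted p = 0.112 for each), with the endothelial miR-126a-3p at -0.30 ± 0.14 (SE). Both passed as lower without WT library 4 (camera adjusted p = 0.0346 for each) and without WT library 4 and db/db library 6 (0.0335 for each). Over the leukocyte list alone 1 member was lower, miR-223-3p.

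Erythroid miRNAs ranked higher in db/db libraries as a list. Of 7 members 6 had positive values, with a median log2 fold change of 0.53 (camera adjusted p = 0.0118; adjusted p = 0.409 with an estimated correlation). Each arm of miR-486a and miR-486b, which share 1 locus, was among the positive ones. Of the other members miR-144-3p stood at 0.60 ± 0.87, miR-144-5p at -0.53 ± 0.63 and miR-451a at 0.26 ± 0.27 (log2 fold change, SE). None of the 7 passed over all miRNAs, and 2 were higher when adjusted over the list alone, miR-486a-5p and miR-486b-5p. With these 2 taken as 1 the list did not pass (camera adjusted p = 0.108). The mean of its members, which that merge could not move far, was 0.26 ± 0.33 in place of 0.29 ± 0.30 (log2 fold change, SE). The call was also lost without a trend (camera adjusted p = 0.110) and without db/db library 2 (0.0516) or 6 (0.0795). miR-451a, the most abundant miRNA of red blood cells, averaged 1234 ± 379 RPM in WT and 1822 ± 1171 RPM in db/db libraries (SD, n = 6 each; log2 fold change 0.26 ± 0.27, SE; limma adjusted p = 0.717). Its log2 fold change ranged from -0.01 to 0.72 with 1 library left out, and was 0.56 by edgeR (adjusted p = 0.135) and 0.60 by DESeq2 (adjusted p = 0.487).

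**Figure D2:**
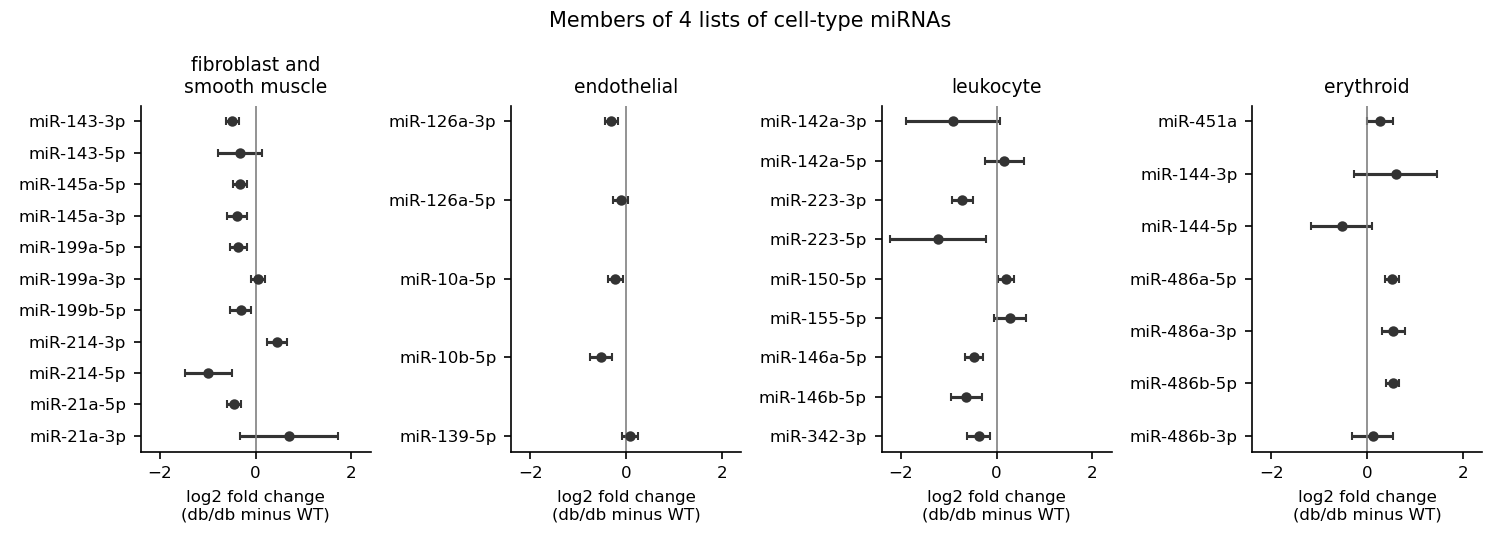
Each panel plots the tested members of 1 list of cell-type miRNAs; the x axis is the log2 fold change of db/db minus WT (6 libraries each), and bars are the standard error. The fibroblast and smooth muscle members have a median of -0.33 and the erythroid members a median of 0.53.

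miRNAs earlier described in mitochondria did not pass as a list. Of 16 measured members 12 had negative values, with a median log2 fold change of -0.30 (camera adjusted p = 0.156). None passed over all miRNAs; adjusted over the list alone, miR-92a-3p was higher and miR-21a-5p lower. miR-378a-3p (-0.10 ± 0.12) and miR-181c-5p (-0.29 ± 0.26) differed by less than 2 standard errors, as did miR-320-3p (0.34 ± 0.22); miR-146a-5p stood at -0.47 ± 0.19 (SE; limma adjusted p = 0.504). Muscle miRNAs had 4 of 6 values below 0 (median -0.26, camera adjusted p = 0.171). Among those encoded in myosin gene introns, miR-208a-3p (Myh6) averaged 68.6 ± 42.4 RPM in WT and 29.6 ± 17.1 RPM in db/db libraries (SD, n = 6 each; limma adjusted p = 0.504), and miR-499-5p (Myh7b) stood at -0.26 ± 0.16 (SE). The other arm of miR-208a, miR-208a-5p, averaged 594 RPM over all libraries and stood at -0.16 (log2 fold change, limma unadjusted p = 0.378). miR-208b-3p (Myh7) and the liver miRNA miR-122-5p averaged under 13 RPM in both genotypes.

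The other lists did not pass. Over each list alone, cardiac stress miRNAs (12 tested, camera adjusted p = 0.519) had 2 lower members, miR-195a-5p and miR-21a-5p. The glucose and lipid list had miR-143-3p lower (limma camera adjusted p = 0.365), the miR-15, miR-16 and miR-195 family had miR-195a-5p lower (limma camera adjusted p = 0.218), and the miR-23, miR-24 and miR-27 clusters, 11 members tested in each, had miR-24-3p lower (limma camera adjusted p = 0.112). The miR-17-92 cluster, with 16 tested, had miR-92a-3p higher (limma camera adjusted p = 0.459). The Dlk1-Dio3 cluster (48 tested, camera adjusted p = 0.667) had 1 higher and 1 lower, the miR-434 arms. No member passed over the list alone in the miR-181 family (camera adjusted p = 0.141), the let-7 family (0.283), the Sfmbt2 cluster (0.283), the miR-34 family (0.491), the miR-30 family (0.594), the liver and epithelial list (0.594), the miR-29 family (0.702), the neural list (0.977) or the miR-378 family (0.977). Median and camera direction had opposite signs in the neural and miR-378 lists, and median and mean had opposite signs in the cardiac stress, let-7, miR-29, miR-34, miR-378 and miR-23, miR-24 and miR-27 lists. With an estimated correlation 0 of the 21 lists passed, and fry, which asks whether a list's members move on balance in 1 direction, called 0. The mixed test of fry, which disregards direction, called 4: the mitochondrial (fry adjusted p = 0.0256), leukocyte (0.0298) and cardiac stress (0.0129) lists and the miR-23, miR-24 and miR-27 clusters (0.0390).

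Whole profiles did not separate the genotypes over all miRNAs tested. The mean distance between libraries of different genotype exceeded that within genotypes by 0.145 (exact permutation test, one-sided, p = 0.238). At a mean of at least 10 RPM, an alternative setting, it did so by 0.559 (exact permutation test, one-sided, p = 0.0433). That p was not adjusted over the several settings run. WT library 4 and db/db library 6 stood apart from the rest on the first principal components. They also had the fewest recovered reads (551591 and 412749) and the highest shares of reads in unnamed rows (0.160% and 0.157%). Depth was not tested as the cause. Without these 2, limma called 0 miRNAs, with 47 at an unadjusted p under 0.05, and miR-22-3p had a log2 fold change of -0.56 (limma adjusted p = 0.108).

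A grouping by sample number was noticed in these libraries only after the fits above had been run, when a random split much like it gave the most calls. Between libraries 4 to 6 and 1 to 3, with genotype in the model, limma called 17 miRNAs, 8 higher and 9 lower in 4 to 6. Among them miR-125a-5p, a relative of miR-125b, averaged 17150 RPM in libraries 1 to 3 and 12004 RPM in 4 to 6 (limma adjusted p = 0.00180). The 17 also held miR-22-3p (0.38), miR-143-3p (0.42), miR-92a-3p (-0.57) and miR-208a-3p (1.64), as log2 differences of 4 to 6 minus 1 to 3. Their limma adjusted p were 0.0355, 0.00970, 0.00181 and 0.0416. Each of them had the opposite sign in db/db minus WT, while miR-451a (0.76, limma adjusted p = 0.0160) had the same sign in both. Both genotypes had 3 libraries on each side, and the labels name no batch. Of 100 shuffles of the db/db numbers, the real order included, 18 gave a halving with as many calls. With it as a factor limma called 10 miRNAs between the genotypes. miR-486a-5p, miR-486b-5p, miR-92a-3p and miR-434-3p were the 4 higher in db/db libraries. The 6 lower were miR-22-3p, miR-143-3p, miR-195a-5p, miR-21a-5p, miR-223-3p and miR-24-3p. With the same factor edgeR called 9, without miR-434-3p, miR-21a-5p and miR-24-3p and with miR-125b-5p and miR-451a (both higher). Within libraries 1 to 3 and within 4 to 6 limma called 0 (44 and 36 at an unadjusted p under 0.05). Of the lists, with the factor camera called the fibroblast and smooth muscle list lower (adjusted p = 0.00457) and the erythroid list higher (adjusted p = 0.00187). With an estimated correlation camera called 0 with that factor. Within 4 to 6 camera called the erythroid list higher and the miR-181 family and the miR-23, miR-24 and miR-27 clusters lower (adjusted p = 0.0268 each). Within 1 to 3 the lowest camera adjusted p was 0.0593. Between the numbers the muscle list (camera adjusted p = 0.00119) and the miR-15, miR-16 and miR-195 family (0.00328) were higher in 4 to 6.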

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

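Tests of the number grouping, the depth covariate, the shuffled numbers and the reassigned labels were chosen only after that grouping was seen. 58 groups of 6 values were searched for a library far from the others, and 4 stood out, where chance flags about 1 in 20, or 2.9 here. In WT, miR-133a-3p was 367506 RPM in library 1 and at most 324643 in the others, a gap of 0.700 of the range. miR-122-5p, near the floor, was 27.5 RPM in WT library 1 against at most 4.99 in the other WT libraries (0.818 of the range). Among db/db libraries it was above 0 in library 3 alone, a gap of 1, the whole range. Recovered reads were 1382046 in db/db library 5 and at most 773784 in the others (0.628 of the range).

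Libraries numbered 1 to 3 and 4 to 6 differed in 17 miRNAs, while the other ways of halving the 6 numbers gave at most 1. A difference in depth does not account for it: with recovered reads as a covariate 29 miRNAs were called, and depth differed by 0.10 on the log2 scale (exact permutation p = 0.697). Chance is not excluded. Among 100 single splits within each genotype, 2 gave as many calls, the real one included (highest other 22). This halving was picked from the data as the best of 10, however. With the same choice 18 of 100 shuffles of the db/db numbers, the real order included, did as well (highest other 27). Shuffles that keep db/db 1 to 3 together rebuild this halving, so this test could hardly have excluded chance. A batch of isolation, library or sequencing is a further candidate explanation that the labels neither name nor exclude, and the age or litter of the mice stays untested. For the 10 miRNAs called between genotypes with this factor, only the real 1 of 100 reassignments of genotype gave as many (highest other 9). That test takes as given a factor that was picked from the data and added after the planned fit gave 1 call. Chance is therefore not excluded there either.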

How the results depend on the processing

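Alternatives with a mean of at least 100 RPM, named rows alone, without WT 4 and db/db 6, the 2 miR-486 rows as 1, numbers 1 to 3 and 4 to 6 as a factor, and edgeR with the block or that factor were chosen after seeing the data. Against 1 changed miRNA, limma called 0 with a pseudocount of 0.1 or 10 RPM, no filter, a mean of at least 10 or 100 RPM, quantile normalization, no trend, named rows alone, or without WT 4 and db/db 6. It called 2 after median-of-ratios scaling, 1 with library weights, 10 with numbers 1 to 3 and 4 to 6 as a factor. edgeR called 3, or 9 with that factor. DESeq2 called 13, over the fewer rows to which it gave an adjusted p. The cause of these differences was not tested. Leaving out 1 library gave 0 to 7 calls: 0 without WT 2, WT 4, WT 5, WT 6, db/db 1, db/db 2 or db/db 3, 6 without WT 1 or WT 3, 3 without db/db 4 and 7 without db/db 5. The adjusted p of miR-22-3p then ranged from 0.00719 to 0.311 (0.0860 without WT 2, 0.0992 without WT 4, 0.167 without WT 5, 0.150 without WT 6, 0.101 without db/db 1, 0.311 without db/db 2 and 0.118 without db/db 3). Its log2 fold change was negative under every alternative run.

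Against 2 lists, camera called 1 after median-of-ratios scaling, after rescaling without the 10 most abundant or with the 2 miR-486 rows as 1, 3 at a mean of at least 100 RPM (erythroid, let-7, and miR-23, miR-24 and miR-27), 4 without WT 4 and db/db 6 (endothelial and leukocyte gained), and 0 without a trend, with an estimated correlation or by fry. The fibroblast call was lost after both rescalings and at 100 RPM. Leaving out 1 library gave 0 to 4 lists, 0 without db/db 2 or db/db 6 and 4 without WT 4 (the same 2 gained). The separation of profiles rose to 0.559 at a mean of at least 10 RPM (exact permutation p = 0.0433) and ranged from -0.230 to 0.514 with 1 library left out, below 0 without db/db 1, 2, 3 or 6. The difference in the share of the 10 most abundant ranged from -0.146 to 1.07 percentage points. The log2 fold change of miR-378a-3p turned to 0.0234 after quantile normalization, and that of miR-451a ranged from -0.0125 (without db/db 6) to 0.723 (without db/db 1). Over all alternatives the named miRNAs gave 683 values on the same side of the threshold, 58 newly past it, 17 no longer past it and 2 with the opposite sign.

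With the replicate block limma called 9 miRNAs and 4 lists (endothelial and miR-23, miR-24 and miR-27 gained), and edgeR 11 miRNAs. The numbers were not shown to pair the samples: correlations of same-numbered libraries ran from -0.0494 to 0.118, 1 of 6 above 0.1, and 2 of 12 libraries correlated best with their own number. Depth limits what a low value resolves (1 read was 0.724 to 2.42 RPM). Most simulated changes of 1.5-fold and 2-fold were missed over all miRNAs and also at a mean of at least 100 RPM, and depth was not tested as the cause.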

Other observations

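Tests of the arms, of other cells, scaling and red blood cells, of miR-486 as 1 and of miRNAs with a mean of at least 100 RPM were chosen only after the results were seen, and the criteria for scaling, red blood cells and miR-486 were tightened after their values were seen, which moved the first 2 from excluded to open and the last from fitting to open. Over 142 hairpins with both arms tested, the log2 fold changes of the arms had r = -0.21 (rho = -0.15), and over the 19 with both arms at 100 RPM or more r = 0.55 (rho = 0.48; adjusted permutation p = 0.0154 for each r, 2 correlations, 100000 permutations). These are correlations across hairpins, which are not independent replicates. No arm ratio passed (limma, 9 at an unadjusted p under 0.05; 34 of 100 splits of the libraries gave as many, highest other 17). The ratio of the miR-434 arms had the smallest p (limma adjusted p = 0.199; 0.0560 to 0.532 with 1 library left out). miR-434-3p had 0 to 36 reads in WT and 19 to 75 in db/db libraries, and miR-434-5p 13 to 37 in WT and 3 to 14 in db/db.

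Differences between the genotypes at an unadjusted p under 0.05 numbered 33 among the 147 miRNAs with a mean of at least 100 RPM and 25 among the other 499. The abundant ones include miR-24-3p (-0.36 ± 0.12) and miR-31-5p (0.59 ± 0.21; log2 fold change, SE; limma adjusted p = 0.198 and 0.268). Of 100 splits of the 12 libraries 6 gave as many abundant ones (highest other 47), so chance is not excluded. For the 1 changed miRNA 12 of 100 splits gave as many (highest other 19), and for the 2 lists 18 of 100 (highest other 4), so chance is excluded for neither. With the number grouping as a factor 13 of 100 reassignments gave 2 lists (highest other 5). The split with 19 calls set WT 1, WT 3 and db/db 1, 2, 3 and 6 against the rest.

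The fibroblast and smooth muscle list ranked lower in db/db libraries, but not with an estimated correlation (camera adjusted p = 0.409). Under median-of-ratios scaling its median was -0.27 in place of -0.33, and the call was lost (camera adjusted p = 0.0748). The mean of its members moved from -0.22 ± 0.12 to -0.16 ± 0.13 (SE; exact permutation p = 0.106 and 0.234). The median of all rows tested moved from -0.039 to 0.0044. Why the call ended was not tested, and scaling to a common total stays open. Fewer reads from other cardiac cells, if fibroblasts and smooth muscle cells fell together, would lower 2 sets of members alike. These were the miR-143 and miR-145 members (-0.38) and the miR-199 and miR-214 members (-0.23). Their difference had an exact permutation p of 0.587, which leaves this open, since the sets differ by less than their spread between libraries. A loss of 1 of these cell types alone was not tested. The second set was itself split. In it miR-214-5p (-0.99 ± 0.49, mean 39.3 RPM), miR-199a-5p (-0.36 ± 0.18) and miR-199b-5p (-0.31 ± 0.21) were negative. Positive values were those of miR-214-3p (0.45 ± 0.22, mean 538 RPM) and miR-199a-3p (0.06 ± 0.14, mean 2533 RPM; log2 fold change, SE). The call was also lost after rescaling without the 10 most abundant (camera adjusted p = 0.0920), without a trend (0.110), at a mean of at least 100 RPM (0.140), and without db/db 2 (0.0551) or db/db 6 (0.0795), and a change with genotype itself stays open.

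The erythroid list ranked higher, but not with an estimated correlation (camera adjusted p = 0.409). With miR-486a-5p and miR-486b-5p as 1 the list did not pass (camera adjusted p = 0.108), so the call depended on counting them as 2. The mean of its members was 0.26 ± 0.33 in place of 0.29 ± 0.30 (SE). Merging 2 members with nearly equal values could not move that mean far, so the mean cannot decide. Listing 1 locus as 2 miRNAs was thus needed for the list to pass. As an explanation of the higher mean it stays open. The members from other loci each differed by less than their standard error. They were miR-451a (0.26 ± 0.27), miR-144-3p (0.60 ± 0.87) and miR-144-5p (-0.53 ± 0.63; log2 fold change, SE). Residual red blood cells are a further candidate explanation: with log2 miR-451a as a covariate the mean of the other 6 members went from 0.30 ± 0.28 to 0.20 ± 0.20 (SE), too wide to decide. miR-486a-5p alone stayed at 0.52 (95% interval 0.18 to 0.87), and it is also a muscle miRNA, so a change in heart muscle stays open. The list call was also lost without a trend (camera adjusted p = 0.110), without db/db 2 (0.0516) or without db/db 6 (0.0795).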
